A study of Homo sapiens with 2 samples.

How the data were processed

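The series compares 2 transduced derivatives of the human melanoma line A375SM, labelled NFAT1-shRNA and NT-shRNA, with total RNA of integrity numbers between 9.3 and 9.9. Per the labelling protocol, RNA was amplified to aminoallyl antisense RNA and coupled to Cy5. The extraction protocol names an Illumina kit and chip, which does not go with that dye or with the probe names of the table, so the array maker is left open here. The deposited table holds, per the file headers, 1 value per probe and line for each of 3 measures. The detection p-values were computed by the authors, with no method given in the sources used here. The normalized intensities are on a linear scale as deposited by the authors, some below 0 (5.54% of probes in the NFAT1-shRNA line and 6.08% in the NT-shRNA line), and the normalization and the way the 3 replicates were combined are not given in the sources used here. An error stands beside each deposited intensity in the same unit, and whether it is a standard deviation, a standard error or a modelled error is not stated. The table also holds the authors' log2 ratio of NFAT1-shRNA to NT-shRNA and the authors' p-value for it, with no statement that this p-value is adjusted. No ratio is given for 17038 probes (58.4%).

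The deposited columns were checked against each other. The intensities differed in level, with medians over all probes of 21.3 in the NFAT1-shRNA line and 17.2 in the NT-shRNA line, and over genes with a ratio the median log2 quotient was 0.30. The authors' log2 ratio had a median of -0.02 over genes, so it is centred and is not the plain quotient. Its offset from the quotient had a median of -0.34 for probes with a mean intensity under 300 and -0.15 for those over 8000. For 29 probes it departed by more than 1 from the median offset. The standard error implied by the authors' p-value was a median 1.03 times the error propagated from the 2 deposited errors (5th to 95th percentile 0.748 to 1.28), where the log2 ratio was over 1 implied standard error. The series matrix held the same intensities within 1e-06. A normalized intensity over 60000 was seen for 6 probes in either line.

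A test across arrays had been planned before the data were examined, with moderated linear models, gene set tests and chance regroupings of the arrays. It could not be run, because the table gives 1 combined value per line and no value per array. For that case the plan foresaw no count of changed genes. The counts given here are a departure from it, decided after the table was seen to hold the authors' own p-values. Each gene's authors' p-value was adjusted by the Benjamini-Hochberg method over all genes with a ratio, taken as two-sided, and genes under 0.05 are called changed. These p-values carry whatever replicate spread the authors' error holds, which was not examined. Intervals of 95% are the authors' ratio with the propagated error, taken as a normal standard error. Alternatives in scale use the log2 difference divided by the propagated error in the same way.

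Of the probes, 25650 name 1 gene, 836 several and 2701 none, and only the first were used. Entrez numbers were matched to a RefSeq gene table of the GRCh38.p14 assembly for current symbols, with 25400 of these probes matched and the file's symbol kept otherwise. A gene was represented by its probe of highest mean intensity over both lines, which gave 19412 genes, 9516 of them with a ratio. Where a signal was detected (detection p-value under 0.01) in 1 line only, a bound is given as "at least". It sets the bright value against the higher of the dim value and the lowest detected signal of that line (78.3 in the NFAT1-shRNA line and 60.4 in the NT-shRNA line), with the median shift between the lines removed. No fold is given where both were undetected, although the mean of the NFATC2 probes and the list medians take in the authors' ratios of such probes, and values under alternatives are given where their sign changed. List medians were also computed with each gene detected in 1 line only at its bound or at the authors' ratio, whichever was smaller, and at 0 where no bound held. This moved the medians of the 20 lists inside the middle 95% by at most 0.027.

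The 24 gene lists were fixed before the data were examined. Each list's median log2 ratio was taken relative to the median of all genes and placed among 10000 random lists of the same size matched on mean intensity in 20 bins. This percentile describes these lines and is no test across genes. Genes named are NFATC2, CXCL8 and MMP3, the 10 largest rises and 10 largest falls by the authors' ratio among genes above the median intensity of the line in which they are higher, and up to 3 members per list with the largest absolute ratio. A gene that this rule takes among the falls is not reported here, for a reason that does not rest on its values. Genes outside this rule are said to be named after their values were seen. Single values of other probes were looked up for only some of the named genes, so silence about other probes is no sign of agreement. All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

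The calling step was tested on simulated data, with known changes in 200 genes drawn with the propagated errors of the NFAT1-shRNA against NT-shRNA comparison. Of the simulated changes over 9516 genes, 23.5% of those of log2 size 0.5 were recovered, 66.2% of size 1 and 90.6% of size 2, and 1 of 9316 unchanged genes was called. The simulated noise had the size that the test assumed, so few false calls follow from that setting. They give no rate of false calls among genes called from the authors' p-values. The median propagated error of the log2 ratio was 0.213. Of 200 random lists of 25 genes, 7.0% lay outside the middle 95%, and 99.5% of lists raised by 0.3 were found above it. Alternatives covered the scale between lines (plain quotient, common median, quantile normalization, offset of 50 with and without a common median), filters on dim or undetected probes, the choice of probe, the threshold and the series matrix values.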

Results

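Gene expression was measured by single-colour Cy5 microarray in A375SM, a human melanoma cell line selected for high metastatic capacity. Cells had been transduced with a lentivirus carrying a short hairpin RNA (shRNA) against NFAT1, a calcium-regulated transcription factor encoded by NFATC2, or with a non-targeting (NT) shRNA, and the brightest 50% of GFP-positive cells had been sorted. The comparison asks which transcripts differ between the line labelled NFAT1-shRNA and the line labelled NT-shRNA. The design text gives 3 biological replicates per line, but the values used here are 1 combined intensity per probe and line, each with the authors' error, so no spread between replicates could be computed. Of 29187 probes, 9185 were detected at a detection p-value under 0.01 in the NFAT1-shRNA line and 8783 in the NT-shRNA line. The authors' deposited table gave a log2 ratio and a p-value for 12149 probes. With each gene represented by its brightest probe, 9516 genes had a ratio. Among genes with a mean intensity over 100, the median relative error was 7.32% in the NFAT1-shRNA line and 9.63% in the NT-shRNA line. The number of arrays limits the precision of all values.

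NFATC2, the gene targeted by the shRNA, was not lower in the line labelled NFAT1-shRNA. Its brighter probe (Entrez gene 4773) read 279.2 with a deposited error of 15.7 in the NFAT1-shRNA line and 199.4 with an error of 15.2 in the NT-shRNA line. The log2 ratio of NFAT1-shRNA to NT-shRNA in the authors' deposited table was 0.12, with a 95% interval from the deposited errors of -0.15 to 0.39 and a Benjamini-Hochberg adjusted p of 0.819. The other NFATC2 probe read 41.6 and 57.8 and was detected in neither line. With the mean of the ratios of both probes the gene's value was -0.06. The plain quotient of the intensities of the brighter probe was 0.49 on the log2 scale, where the median gene stood at 0.30. The array therefore gave no lower NFATC2 transcript level by which the labels could be checked, and each direction below is that between the lines as labelled. What the NFATC2 probes cover relative to the shRNA's target sequence is not given in the sources used here. Of the other NFAT genes, named after their values were seen, NFATC3 had a log2 ratio of 0.13 and NFAT5 of 0.04 in the authors' deposited table, neither past the threshold, and no NFATC1 or NFATC4 probe was detected.

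**Figure D1:**
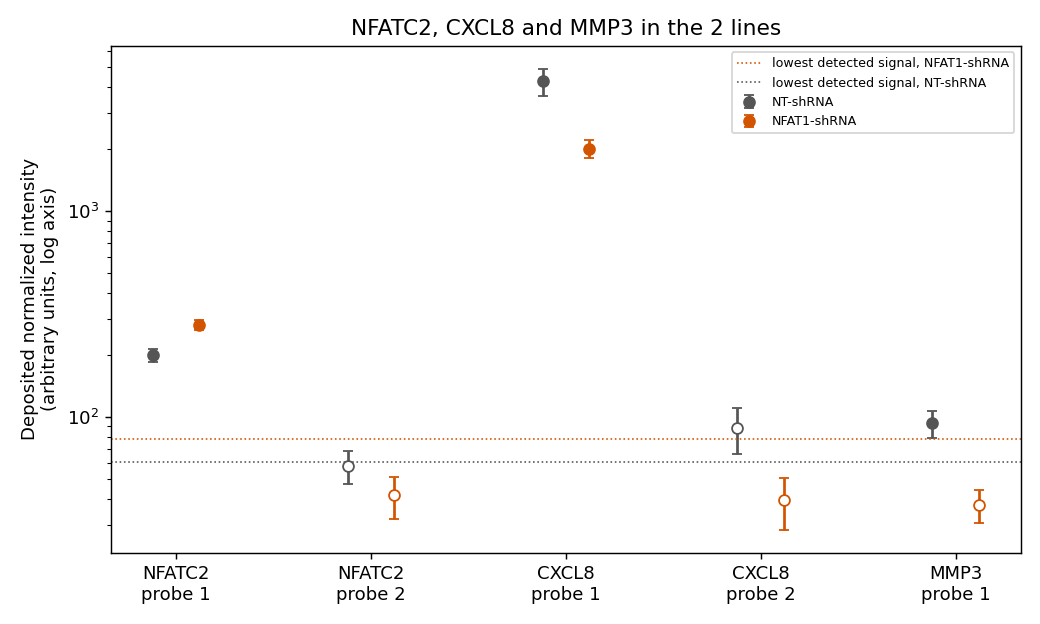
Deposited normalized intensity (arbitrary units, log axis) of each probe of NFATC2, CXCL8 and MMP3 in the NT-shRNA line (grey) and the NFAT1-shRNA line (orange). Each point is the authors' combined value of 1 line, bars are the deposited errors, open points were not detected at a p-value under 0.01, and dotted lines mark the lowest detected signal of each line. The brighter NFATC2 probe read 279.2 in the NFAT1-shRNA line and 199.4 in the NT-shRNA line, and the brighter CXCL8 probe read 2014 and 4268.

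CXCL8 (interleukin-8, a neutrophil-attracting chemokine) and MMP3 (stromelysin-1, a matrix-degrading protease) are the genes this study is known to have followed up. Both were lower in the line labelled NFAT1-shRNA. The brighter CXCL8 probe (Entrez gene 3576) read 2014 with an error of 200 against 4268 with an error of 637. In the authors' deposited table its log2 ratio was -1.26, 2.40-fold higher in the NT-shRNA line, with an interval of -1.77 to -0.75 and an adjusted p of 0.000303. The other CXCL8 probe read 39.5 in the NFAT1-shRNA line and 88.5 in the NT-shRNA line and was detected in neither. MMP3 (Entrez gene 4314) read 37.4 with an error of 6.85 against 93.1 with an error of 14.2, and it was not detected in the NFAT1-shRNA line. Its log2 ratio in the authors' deposited table was -1.69, with an adjusted p of 0.0345. Against the lowest detected signal of the NFAT1-shRNA line, MMP3 was at least 1.47-fold higher in the NT-shRNA line. The list made of these 2 genes had a median of -1.46 relative to all genes (percentile 0 of random lists of matched signal), or -0.90 (percentile 0.07) with genes detected in 1 line only set at their bound. Both members fell, also when adjusted over the list alone. The study chose this pair on these samples, so the direction is not independent evidence.

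Across all genes, 718 of 9516 (7.55%) changed at an adjusted p under 0.05 computed from the p-values of the authors' deposited table. Of these, 319 were higher and 399 lower in the line labelled NFAT1-shRNA. A change of at least 2-fold was seen for 120 of them, 66 higher and 54 lower. At an unadjusted p under 0.05 the authors' deposited table gave 1828 of these genes, where 475.8 would be expected with no difference. How the authors computed these p-values is not given in the sources used here, so the counts are only as firm as that calculation. The plain quotient of the intensities, with no centring, called 2278 genes (342 at least 2-fold), and an offset of 50 with a common median called 909 (73 at least 2-fold). The balance of directions rests on the centring of the ratio. Of the calls, 44.4% were higher with the authors' ratio, 93.5% with the plain quotient of the intensities and 93.8% after an offset of 50 with no centring, since the NFAT1-shRNA intensities were 1.23-fold higher for the median gene.

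Among genes above the median level, the 10 that fell most in the line labelled NFAT1-shRNA included FST, PLAC8, FLT1, VDAC1, PAPSS2, TMEM45A, FZD4, COX6B1 and CAPG. Follistatin (FST), a secreted antagonist of activins, read 88.1 against 672.6, and its log2 ratio in the authors' deposited table was -3.21 with an interval of -3.64 to -2.77. PLAC8 read 130.1 against 672.4 with a log2 ratio of -2.70 in the authors' deposited table, and FLT1, a receptor for vascular endothelial growth factor, read 101 against 490.9 with -2.59. All other FLT1 probes were dimmer and detected in neither line, so the FLT1 value rests on 1 probe. VDAC1, a channel of the mitochondrial outer membrane, stood at -2.41 in the authors' deposited table, with deposited errors of 26.4% and 31.5% of its signal in the NFAT1-shRNA and NT-shRNA lines and an interval of -3.58 to -1.25. The sulfate-donor synthase PAPSS2 had -2.22, TMEM45A -2.06 and the Wnt receptor FZD4 -1.80 in the authors' deposited table. COX6B1, a subunit of cytochrome c oxidase, fell on both of its probes, by log2 ratios of -1.59 and -1.75 in the authors' deposited table. The actin-capping protein CAPG had -1.58 in the authors' deposited table. Adjusted p-values of the genes named here from the authors' deposited table ran from 1.91e-30 for PLAC8 to 0.00388 for VDAC1.

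The 10 that rose most under the same rule were ADGRE1, QPRT, OTOR, PLN, MAP4K4, DHRS2, HGF, UPP1, EDNRA and TCN1. ADGRE1, an adhesion G protein-coupled receptor, read 701.7 against 94.6, with a log2 ratio of 2.56 and an interval of 2.16 to 2.96 in the authors' deposited table. QPRT, an enzyme of NAD synthesis, stood at 2.10 and the secreted protein OTOR at 2.08 in the authors' deposited table. The vitamin B12 binding protein TCN1 read 2646 against 693.4, with a log2 ratio of 1.64 in the authors' deposited table. PLN (phospholamban), DHRS2, UPP1 (uridine phosphorylase) and EDNRA (an endothelin receptor) were not detected in the NT-shRNA line. Against the lowest detected signal there, PLN was at least 3.32-fold, DHRS2 at least 3.75-fold and UPP1 at least 3.23-fold higher in the NFAT1-shRNA line. For EDNRA the bound, here against its own higher NT-shRNA value, was 3.95-fold, larger than the 3.13-fold of the authors' deposited table, so neither is taken as its size. For the kinase MAP4K4 and the growth factor HGF the probes disagreed. In the authors' deposited table the representative MAP4K4 probe had a log2 ratio of 1.98 and the other probe -0.42, while the HGF probes had 1.89 and -0.10. Adjusted p-values of these 10 genes from the authors' deposited table ran from 2.31e-29 for OTOR to 0.00129 for UPP1.

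**Figure D2:**
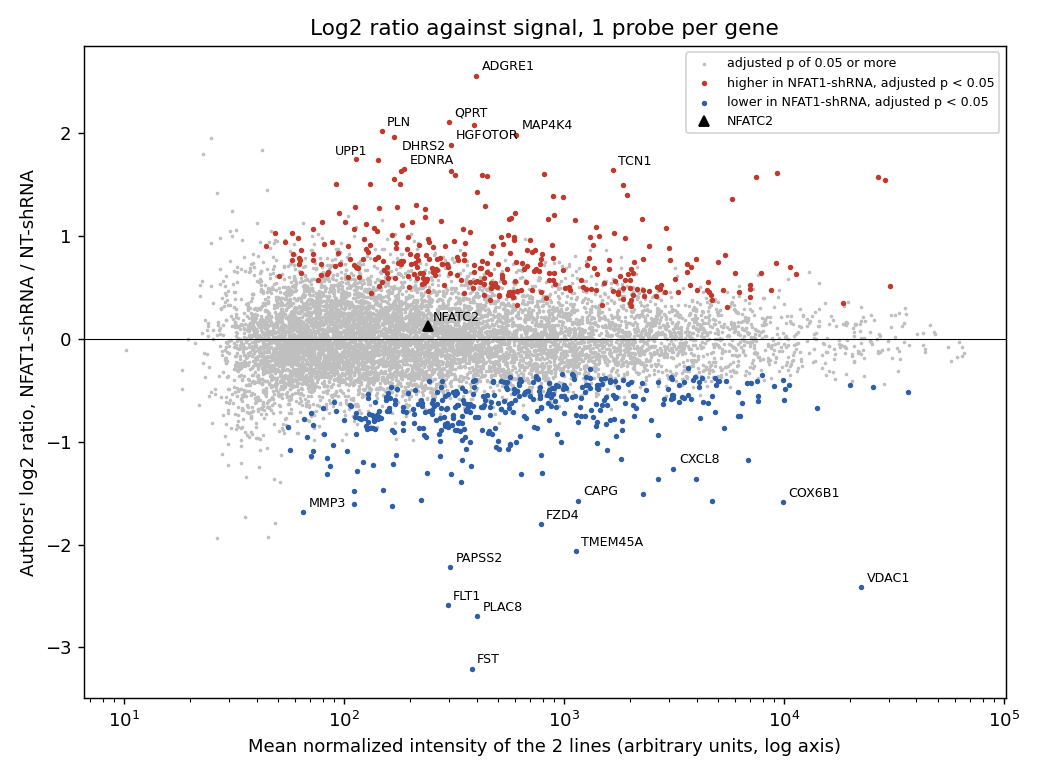
Log2 ratio of NFAT1-shRNA to NT-shRNA from the authors' deposited table (vertical axis) against the mean normalized intensity of the 2 lines (horizontal log axis, arbitrary units), 1 point per gene. Genes at an adjusted p under 0.05 are red (319 higher) or blue (399 lower) and others grey, and the black triangle marks NFATC2 at 0.12, among the grey points.

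As a list, genes of melanocyte differentiation and pigmentation stood higher in the line labelled NFAT1-shRNA. Of 21 measured members, 9 rose, none fell and 12 did not pass, against 10 higher and 1 lower when adjusted over the list alone. By sign alone, 15 ratios were positive and 6 negative. Named after their values were seen, PMEL, MLANA, SOX10, PAX3 and GPNMB were among those that did not pass over all genes. EDNRB, named likewise and counted as a rise, had log2 ratios of 0.88, 0.01 and 1.09 on its probes in the authors' deposited table. The list's median was 0.44 relative to all genes, above all 10000 random lists of matched signal (percentile 100), but only 0.24 (percentile 99.4) with the mean of each gene's probes. Tyrosinase (TYR), the rate-limiting enzyme of melanin synthesis, read 288.6 against 74.6 and had a log2 ratio of 1.63 with an interval of 1.28 to 1.97 in the authors' deposited table. The membrane glycoprotein GPM6B had 1.16 and dopachrome tautomerase (DCT), another melanin enzyme, 1.01 in the authors' deposited table. The 2 dimmer GPM6B probes, not detected in the NT-shRNA line, were at least 2.97-fold and 1.37-fold higher in the NFAT1-shRNA line. Named after its values were seen, MITF, the transcription factor that controls many of these genes, had log2 ratios of -0.50 and 0.60 on 2 probes in the authors' deposited table, neither past the threshold.

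Genes of hypoxia and glycolysis stood lower. Of 30 measured members, 7 fell, 2 rose and 21 did not pass, with 10 lower and 2 higher when adjusted over the list alone. By sign alone, 8 ratios were positive and 22 negative. LDHA, PGK1, VEGFA and HK2, named after their values were seen, were among those that did not pass over all genes. The median was -0.25, at percentile 0 of the random lists, and was -0.25 too with genes detected in 1 line only at their bound. BNIP3, a mitochondrial protein induced by hypoxia, had a log2 ratio of -1.31 in the authors' deposited table and its other probe -1.06. The glucose transporter SLC2A3 had -0.92 in the authors' deposited table. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was not detected in the NFAT1-shRNA line and was at least 1.43-fold higher in the NT-shRNA line (adjusted p 0.0484 from the authors' deposited table). The 2 members that rose, named after their values were seen, were the carbonic anhydrase CA12 at 0.76 and PFKFB4, an enzyme that regulates glycolysis, at 0.77 in the authors' deposited table.

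Of the 4 measured genes of the list with galectin-3, autotaxin and receptors of lysophosphatidic acid, 2 fell and 2 did not pass, the same counts as when adjusted over the list alone. Its median was -0.72, at percentile 0.01, or -0.53 (percentile 0.08) with genes detected in 1 line only at their bound. Autotaxin (ENPP2), which makes lysophosphatidic acid, had a log2 ratio of -1.47 with an interval of -1.91 to -1.02 in the authors' deposited table. The receptor LPAR1 was not detected in the NFAT1-shRNA line and was at least 1.80-fold higher in the NT-shRNA line. Galectin-3 (LGALS3) had -0.23 in the authors' deposited table, with an interval of -0.51 to 0.06.

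The other 20 lists had medians inside the middle 95% of random lists, although several held members that changed in both directions. Of 14 genes of inflammatory cytokines, chemokines and NF-kB feedback, 3 rose and 1 fell, with a median of -0.10 (percentile 14.6). CXCL8 was not in this list. IL1A had a log2 ratio of 1.30 and the chemokine CCL20 -0.88 in the authors' deposited table, and IL1B, not detected in the NT-shRNA line, was at least 1.35-fold higher. Among 22 genes of metalloproteinases, their inhibitors, the plasminogen system and cathepsins, 2 rose and 3 fell, with a median of -0.04 (percentile 29.4). MMP3 was not in this list, and none of the list's matrix metalloproteinases passed. The urokinase receptor PLAUR had -0.74 and the lysosomal protease CTSD 0.79 in the authors' deposited table, and the plasminogen activator inhibitor SERPINB2 was at least 1.73-fold higher in the NFAT1-shRNA line. For IL1B and SERPINB2 the interval from the deposited errors included 0. Of 26 matrix and integrin genes, 4 rose and 4 fell, with a median of 0.02 (percentile 65.8). Fibronectin (FN1) had -1.51 and osteopontin (SPP1) 0.99 in the authors' deposited table, while COL6A2 had -0.98 and did not pass.

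Among 22 markers of the invasive melanoma state, 1 rose and 3 fell, with a median of 0.01 (percentile 54.5). The ectonucleotidase NT5E had a log2 ratio of -0.85 in the authors' deposited table, and the AP-1 factor FOSL1, not detected in the NT-shRNA line, was at least 1.51-fold higher. IL1RAP, with the largest ratio of the list, was also not detected there and did not pass. Its bound, against its own NT-shRNA value, was 2.09-fold. That is larger than the 2.02-fold of the authors' deposited table, so neither is taken as its size. Of 25 AP-1 and MAPK feedback genes, 5 rose and 5 fell, with a median of -0.03 (percentile 31.8). PHLDA1 had 1.03 in the authors' deposited table, and the feedback inhibitor SPRY1 was at least 1.90-fold higher. Of 14 antigen presentation genes, 4 rose and 1 fell, with a median of 0.03 (percentile 66.1). The immunoproteasome subunits PSMB9 and PSMB8 had 1.17 and 1.11 and beta-2-microglobulin (B2M) 0.64 in the authors' deposited table. Among 21 interferon response genes, 2 rose and none fell, with a median of 0.13 (percentile 92.0). IFI6 had 0.70 and the double-stranded RNA sensor EIF2AK2 0.57 in the authors' deposited table. Of 26 genes of the unfolded protein and amino acid stress responses, 3 rose and none fell, with a median of 0.11 (percentile 93.6). The cystine transporter SLC7A11 had 1.20 and the serine synthesis enzyme PHGDH 0.83 in the authors' deposited table, and CHAC1, which degrades glutathione, was at least 2.09-fold higher.

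Of 24 p53 target and cell death genes, 2 rose and 1 fell, with a median of 0.12 (percentile 94.0). BTG2 had a log2 ratio of 0.95 and the cyclin-dependent kinase inhibitor CDKN1A 0.91 in the authors' deposited table. Of 40 cell cycle genes, CDK6 rose and CCNB1 fell, with 0.76 and -0.63 in the authors' deposited table, and the median was 0.08 (percentile 90.1). Of 17 angiogenesis genes, 1 rose and 2 fell, with a median of -0.15 (percentile 5.57), FLT1 and ANGPTL4 being lower and FGFR1, at 0.87 in the authors' deposited table, higher. Of 18 NFAT and calcineurin genes only NFATC2IP, an NFAT-interacting protein, passed the threshold, at -0.61 in the authors' deposited table, and the median was 0.06 (percentile 72.9). Among 29 ribosomal protein genes, 2 rose (RPL7 and, named after its values were seen, RPS27), with a median of 0.13 (percentile 97.0). Of 8 reference genes 1 rose (B2M), with a median of 0.08 (percentile 75.8).

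No member passed among 11 genes of epithelial and mesenchymal adhesion (median -0.08, percentile 27.2) or 25 of sterol synthesis (median 0.11, percentile 92.7). Markers of other cell types were few among the measured genes. Of 7 fibroblast markers only ACTA2 passed, at 0.43 in the authors' deposited table (list median 0.10, percentile 77.7). None passed among 3 keratinocyte markers (0.02, percentile 57.8), 4 leukocyte markers (-0.16, percentile 22.3) and 2 endothelial markers (-0.18, percentile 33.1), where the first value is the list's median. The keratinocyte median changed sign with an offset of 50, with the mean of each gene's probes and among genes detected in at least 1 line. Adjusted over the list alone, the counts of higher and lower members in the matrix and integrin list were 6 and 6, in the invasive list 2 and 3, in antigen presentation 5 and 1, in p53 targets 3 and 1, in the stress responses 5 and 1 and in reference genes 2 and 0. In the other lists described after the galectin-3 list, that adjustment gave the same counts as adjustment over all genes.

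**Figure D3:**
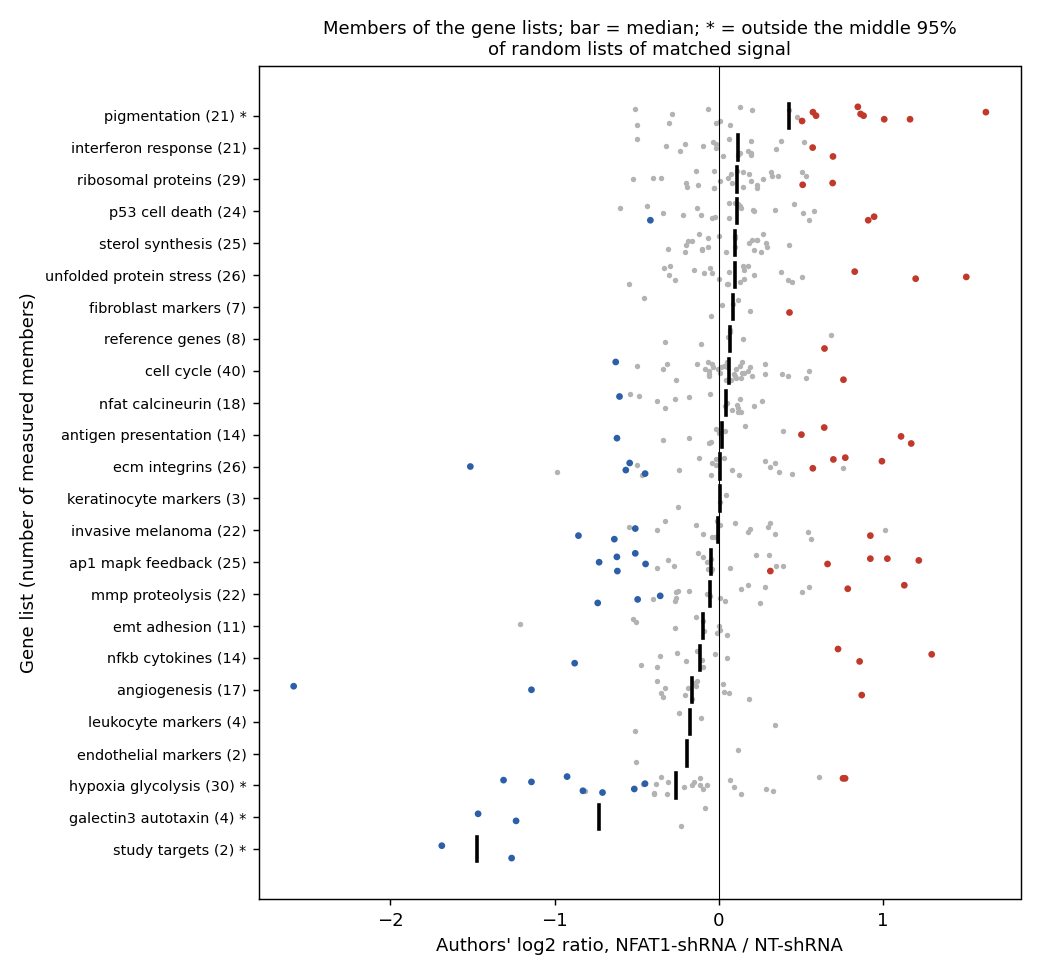
Log2 ratio of NFAT1-shRNA to NT-shRNA from the authors' deposited table (horizontal axis) for each measured member of the 24 gene lists (vertical axis, number of members in brackets). Red and blue points are members higher or lower at an adjusted p under 0.05, grey points did not pass, black bars are list medians and asterisks mark the 4 lists outside the middle 95% of random lists. The pigmentation list lies highest, and the hypoxia and glycolysis list, the galectin-3 list and the followed-up pair lie lowest.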

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

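Probes for which the authors' deposited table gives no ratio were left out of every comparison above, and some of them held a signal in 1 line only. At a detection p-value under 0.01, 19 such probes of single genes were detected in the NFAT1-shRNA line alone and 8 in the NT-shRNA line alone. The genes given here were taken by smallest detection p-value. In the NFAT1-shRNA line, FXYD3 (a regulator of ion transport) read 181.2, the imprinted non-coding RNA H19 read 145.1, TNFSF13B (a B-cell survival cytokine) read 129.5 and coagulation factor F5 read 105.4. Against the lowest detected signal of the NT-shRNA line these were at least 2.43-fold, 1.95-fold, 1.74-fold and 1.41-fold higher. FXYD3 and H19 were each detected on 2 probes. In the NT-shRNA line, NDUFC1 (a subunit of mitochondrial complex I) read 5478, FGL2 read 228.4, MUC15 read 98.8 and the collagen gene COL1A2 read 82.7. FGL2 was at least 3.60-fold, MUC15 at least 1.56-fold and COL1A2 at least 1.30-fold higher there. The NDUFC1 probe read 13.3 with a deposited error of 300.4 in the NFAT1-shRNA line, and the gene's other probe had a log2 ratio of -0.12 in the authors' deposited table. Named after its values were seen, the melanin enzyme TYRP1 read 138.1 in the NFAT1-shRNA line and 15.8, not detected, in the NT-shRNA line, at least 1.85-fold higher. With no value per array, none of these signals was tested.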

How the results depend on the processing

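The plain quotient, the centred offset, the list medians at bounds, the set of all probes, the filter on detection, the mean of probes for single genes and every test on propagated errors were chosen after the data were seen. With 1 value per gene, CXCL8 and MMP3 were lower and under an adjusted p of 0.05 in each setting with a test. Log2 values were -1.39 to -1.07 for CXCL8 (adjusted p 5.81e-06 to 0.00141) and -1.70 to -0.71 for MMP3 (adjusted p 1.46e-05 to 0.0345). In the main setting MMP3 did not reach the stricter limit of 0.01, and adjusted over every probe it stood at 0.0373. The smallest adjusted p-values of MMP3 came from the propagated error and not from the authors' p-value. Without centring, the plain quotient called 2278 genes (342 at least 2-fold) and an offset of 50 called 2393, and NFATC2 passed the threshold as higher, at 0.49 and 0.40. Centring accounts for most of this: shifted to a common median, the quotient called 922 genes and the offset 909 (73 at least 2-fold), and NFATC2 was at 0.18 and 0.17 and did not pass. The series matrix gave 0.49 for NFATC2, being the plain quotient. With the mean of its probes NFATC2 stood at -0.055 and did not pass, since this takes in the undetected probe. At an adjusted p under 0.01, a stricter limit, 423 genes were called. Quantile normalization called 848 genes, of which 640 were among the 718. The 4 lists outside the middle 95% were outside it under each setting, and the mean of probes added the ribosomal proteins (percentile 98.9). The filter on the dimmest 25% of probes removed no tested gene and so tests nothing. Of the other values of named genes under alternatives other than that filter, 835 kept direction and side of the threshold, 55 lost the call, 23 gained it and 17 changed sign, none of them a call in either setting. With the plain quotient and the offset of 50 these were SESN1 (0.028, 0.016), CDH5 (0.071, 0.030), PPIA (0.0025, 0.0023), KRT14 (0.098, 0.076) and NKG7 (0.28, 0.12), negative in the main setting. ESAM, positive there, was -0.167 with a common median, with or without the offset, and -0.27 after quantile normalization. KRT16, also positive there, was -0.0093 after quantile normalization, -0.054 with the centred offset and -0.15 with the mean of probes, and MITF, negative there, was 0.051 with the mean of probes. SESN1, CDH5, NKG7, ESAM and KRT16 were detected in neither line, so the sign of their values says nothing. No paired analysis was possible because the table has no value per array, and for the same reason leaving out arrays, variance models, an unmoderated test, an estimated correlation and chance regroupings were not run. Signal over background limits the dim genes: 8 called genes were detected in neither line.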

Other observations

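The tests in this part were chosen after the results they bear on were seen. Further genes, named after their values were seen, changed on bright probes. AIM2, a sensor of cytosolic DNA, had a log2 ratio of -1.57 in the authors' deposited table, the methyltransferase NNMT -1.36, the protease PRSS23 -1.36, cytoglobin (CYGB) -1.18, the growth factor binding protein IGFBP3 -1.17 and the steroid-metabolising enzyme AKR1C3 -1.08. A second IGFBP3 probe had -1.03 in the authors' deposited table, while a second PRSS23 probe (-0.58) did not pass and a second CYGB probe was detected in neither line. Among rises, the connexin GJB1 had log2 ratios of 1.38 and 1.06 on its 2 probes, TMC6 1.15 and 1.29 and the calcium-binding protein S100A16 1.43 and 1.13 in the authors' deposited table. Of called genes with another probe that had a ratio, another probe had the opposite sign for 10 of 58 higher and 25 of 98 lower genes.

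NFATC2 was not lower in the line labelled NFAT1-shRNA. The tables argue against measurement error of the brighter probe hiding a 2-fold fall, a log2 ratio of -1, since the lower end of the 95% interval was -0.15. They also argue against exchanged columns hiding one, since the lower end with the sign turned was -0.39, although neither excludes a smaller fall. A probe that misses the targeted transcripts stays open, as the other probe was detected in neither line (detection p-value 0.138 in the NT-shRNA line). A hairpin that lowers the protein more than the transcript, or silencing lost before RNA was taken, may also account for it, and neither can be tested here.

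Genes that rose at least 2-fold carried large errors in the NT-shRNA line, with a median relative error of 15.0% over 66 genes. The tables argue against dim signal in that line as the whole cause. Gene sets matched on NT-shRNA intensity had a median of 12.2%, and the rises lay at percentile 99.92 of them. Over 54 falls of at least 2-fold, the NFAT1-shRNA error had a median of 8.79%, at percentile 59.75 of matched sets. The rises were picked by a ratio that uses the same NT-shRNA value, a selection that the matching does not remove. Signal that only 1 probe of a gene shows stays open. Among 12 such genes with another probe, the other probe's median log2 ratio was 0.83 where the NT-shRNA error was over 12.6% and 1.12 where it was lower, a difference of -0.29 (95% bootstrap interval -1.45 to 0.19). Unequal NT-shRNA replicates cannot be examined without values per array.

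Several of the brightest rises carried such errors and were named after their values were seen. TMEM216, HIPK3, MIEN1, CLCN2 and CYP1A2 had log2 ratios of 1.55, 1.57, 1.61, 1.57 and 1.36 in the authors' deposited table. The NT-shRNA error was 21.1% of signal for TMEM216, 19.2% for MIEN1, 19.8% for CLCN2 and 19.3% for CYP1A2, and 2330 on a signal of 12246 for HIPK3. CYP1A2, an enzyme best known from liver, read 8790 in the NFAT1-shRNA line.

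The pigmentation list was higher in the line labelled NFAT1-shRNA. The tables argue against the choice of 1 probe per gene as the whole cause, since with the mean of each gene's probes the list median was 0.24 and still above the middle 95% of random lists, although the size was about halved. A difference in culture or cell population unrelated to the targeted gene remains open, and the hypoxia and glycolysis list, which can follow culture density, also stood apart at -0.25. With 1 line per hairpin, that cannot be told apart from an effect of the hairpin, and whether the difference is biological is a hypothesis only.

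A gain or loss of 1 of 3 or fewer copies over at least 100 measured neighbouring genes could have shifted whole regions. The most shifted window of 100 neighbouring genes had a median log2 ratio of -0.18 and the highest stood at 0.13, short of the 0.4 that such a gain would need if transcripts followed copy number. Across genes, which are not independent replicates, log2 ratios of direct neighbours correlated with Pearson r 0.031 (middle 95% of 2000 shuffles -0.02 to 0.02), and of genes 10 places apart with 0.0066 (-0.02 to 0.02). The value for direct neighbours lay above the range of its shuffles, and the value for genes 10 places apart lay within its range. No window smaller than 100 genes was tested.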
